A study of Mus musculus with 10 samples.

How the data were processed

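RNA from mouse CGR8 embryonic stem (ES) cells, a line of strain SV129, was measured on 10 Affymetrix arrays after one-cycle biotin labelling of total RNA, per the labels' protocols. The groups were untreated ES cells (n = 3), ES cells treated with 1 mM EBIO for 3 days (n = 3), differentiated cells cultured without EBIO (n = 2) and differentiated cells cultured with EBIO (n = 2). The ES arrays of both groups came from passages 25, 26 and 27. The differentiated cells had spent 5 days as embryoid bodies and 10 further days in culture without or with EBIO; the labels give no dose for them. The series' design text calls the samples of each group independent experiments, so p-values measure the spread between such experiments. No array was left out.

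The deposited values are log2 expression values made by the authors with RMA, per the submitters' processing notes, and a label names BioConductor; no version is given in the sources used here. RMA subtracts a background estimated from each array, forces the arrays of a set to 1 distribution and summarises the probes of a probe set. The low end of its scale is therefore compressed: a difference from a dim probe set is understated. From the values, the arrays had been normalized as separate sets. The mean absolute difference between the quantiles of any pair of arrays was at most 0.0931 within the 6 ES arrays and at most 0.0497 within the 4 differentiated arrays, but at least 0.910 between them. Array medians lay near 4.58 in untreated ES cells and 5.67 in untreated differentiated cells. Within a set, differences are comparable; across the sets, a difference near the size of the shift between them cannot be assigned to stage or processing. For an array the number of arrays limits the precision, and no read depth applies.

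The arrays held 45101 probe sets, of which 64 were Affymetrix controls and were left out of the tests. In the platform annotation 34958 probe sets had 1 gene symbol, 932 had several and 9211 had none; only the first kind was named, and the symbols of 34754 of them were brought up to date through a RefSeq gene table. They covered 18193 genes, 9012 of them with more than 1 probe set, and the probe set with the highest mean over the 10 arrays stood for the gene. No coordinates were used here. A gene was tested where it exceeded its array's median (the 50th percentile of all probe sets) on at least as many arrays as the smallest group of the fit held.

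Tests used limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes) on the deposited log2 values, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Each EBIO comparison was fitted on its own arrays. The comparison of untreated differentiated with untreated ES cells, and the difference between the EBIO effects, were fitted on the 4 groups together. Values are given as mean ± SD over arrays, and differences on the log2 scale are EBIO minus control or differentiated minus ES. Gene lists were tested with camera at a preset correlation of 0.01, again with the correlation estimated from the data, and with fry, for lists with at least 5 tested members. The 33 lists held 556 genes, of which 526 had a named probe set. Camera asks whether a list's genes move more than other genes; fry asks whether they move at all, on balance, in 1 direction. Camera's power with an estimated correlation was not measured, and its adjusted p is given beside every list that loses its call. In that form camera rests on the residual degrees of freedom (arrays less groups). These were 4 in the ES comparison, 2 in the differentiated one and 6 in the fits of 4 groups. A call lost there can reflect few arrays as well as correlated genes.

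The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule named 6 genes with the largest rise and 6 with the largest fall per comparison, among genes past the threshold whose groups did not overlap. It also named, per list past camera's threshold or with at least 3 called members, the 2 called members with the largest change in each direction. Kcnn1, Kcnn2, Kcnn3, Kcnn4, Pou5f1, Nanog, T, Nkx2-5, Myh6, Hcn4, Shox2 and Tbx3 were named whatever their result; T and Hcn4 had no named probe set and are not analysed here. Genes named outside this rule are said to be. For the comparison across the separately normalized sets the planned fit was kept, but the part of the rule on lists was not applied, single-gene differences are given without p-values, and the split of calls after quantile normalization of all 10 arrays stands beside the planned one.

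Replicate numbers pair the ES samples by passage: same-numbered arrays came from the same passage, and their deviations from the group means correlated at 0.33, 0.22 and 0.60. EBIO array 2 correlated no better with its own control (0.225) than with control 1 (0.240). The planned ES fit used group means without this pairing, which was run as a block among the alternatives. In differentiated cells the deviations of same-numbered arrays correlated at -0.11, and at 0.11 with the numbers crossed. With 2 arrays a group this is a single value and cannot show whether the numbers mark shared experiments, so no pairing was used. Replicate arrays of a group correlated at 0.982 or higher over all probe sets and none was a copy of another. Among same-group pairs, the mean absolute difference was 0.288 between ES control arrays 1 and 3 and 0.140 between the differentiated EBIO arrays.

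The alternatives were no filter on dim probe sets, a filter at the 75th percentile, the mean of a gene's probe sets, median centring, a new quantile normalization, an intensity trend with robust eBayes, array weights, the replicate number as a block, other groups in the fit, and leaving out each array in turn. Crossed pairing of the differentiated samples, ES cells without both passage-27 arrays, a division of the ES controls between the effects that share them, and list tests after a new quantile normalization were added after seeing the data.

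The tests were checked on 20 simulated data sets per comparison, with 200 genes changed by 1.5, 2, 4 or 8-fold and the real genes' means and moderated variances. In the ES comparison (12096 genes) 32.0% of genes changed by 1.5-fold, 94.1% of those changed by 2-fold and 100% of those changed by 4-fold were recovered. In the differentiated comparison (12338 genes) these shares were 96.2%, 100% and 100%. For the difference between the EBIO effects (13712 genes) they were 6.50%, 60.1% and 98.7%, and for the stage comparison (13712 genes) 35.6%, 92.2% and 100%. Unchanged genes made up 6.09% of calls in the ES comparison, 8.52% in the differentiated comparison (3.41% to 12.1% over the data sets), 5.20% in the stage comparison and 5.10% for the difference. In these simulations, with 200 genes changed, the differentiated comparison, with 2 arrays a group, thus ran above the nominal rate. The real comparison called 65.9% of its genes, so the simulated share cannot be carried over to it. A single simulated data set per comparison was run first; the differentiated one held 13.1%, after which the number was raised to 20. Camera called 1 of 400 unchanged sets in the ES comparison and 0 of 400 in the differentiated one, and all 20 changed sets in each. Genes were simulated independently of each other, so this check does not cover lists of correlated genes. The real estimates reached 0.64 (cholesterol synthesis in ES cells). Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.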

Results

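Gene expression was measured in mouse CGR8 ES cells and in cells differentiated from them, each without and with EBIO, a compound used to open calcium-activated potassium channels of small and intermediate conductance. The series' title names the modulation of these channels, heart cell formation and enrichment for cells resembling pacemaker cells as its subject. The 10 arrays formed 4 groups: untreated ES cells (n = 3), ES cells with 1 mM EBIO for 3 days (n = 3), untreated differentiated cells (n = 2) and EBIO-treated differentiated cells (n = 2). Values are the authors' log2 RMA values.

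The first comparison asked what 3 days of EBIO did to undifferentiated ES cells. Of the core pluripotency genes 13 of 16 fell, of the naive ones 16 of 18, and of smooth muscle genes 5 of 9 rose. Camera called these lists at its preset correlation, and none with an estimated correlation (adjusted p = 0.385, 0.385 and 0.486). Pou5f1, the central transcription factor of pluripotency, fell from 11.88 ± 0.02 to 7.68 ± 0.34 (SD, n = 3 each, adjusted p = 9.9e-07, limma), an 18.3-fold change. Tdgf1, a co-receptor for Nodal, fell from 11.65 ± 0.11 to 4.10 ± 0.39 (n = 3 each), at least 188-fold, since it ended at the dim end of the arrays. In the other direction Acta2, smooth muscle actin, went from 6.60 ± 1.03 to 11.54 ± 0.26 (n = 3 each), 30.6-fold higher. No heart gene list passed camera, and Nkx2-5, an early cardiac transcription factor, measured 5.52 ± 0.41 and 5.45 ± 0.23 (adjusted p = 0.82, not called).

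Of 12096 genes tested in ES cells, 2846 rose and 2567 fell, 1226 and 968 of them by at least 2-fold. The largest falls after Tdgf1 were those of Nr0b1 (-6.73), Fbxo15 (-6.12), Sycp3 (-6.09), Tcl1 (-6.03) and Ifitm1 (-5.93) on the log2 scale. The largest rises were those of Fosl2 (5.14), an AP-1 transcription factor, Vgll3 (5.13), a TEAD cofactor, Cdh2 (5.06), which encodes N-cadherin, Anxa2 (5.05), Ccn1 (5.01), a matricellular target of YAP, and Acta2 (4.94). Standard errors of the named genes' changes ran from 0.11 to 0.44. Tdgf1, Nr0b1, Fbxo15, Sycp3 and Tcl1 ended at 3.67 to 4.38, and Fosl2 and Vgll3 began at 3.64 and 4.08, under the array medians, so these changes are lower bounds and their order is not resolved.

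**Figure D1:**
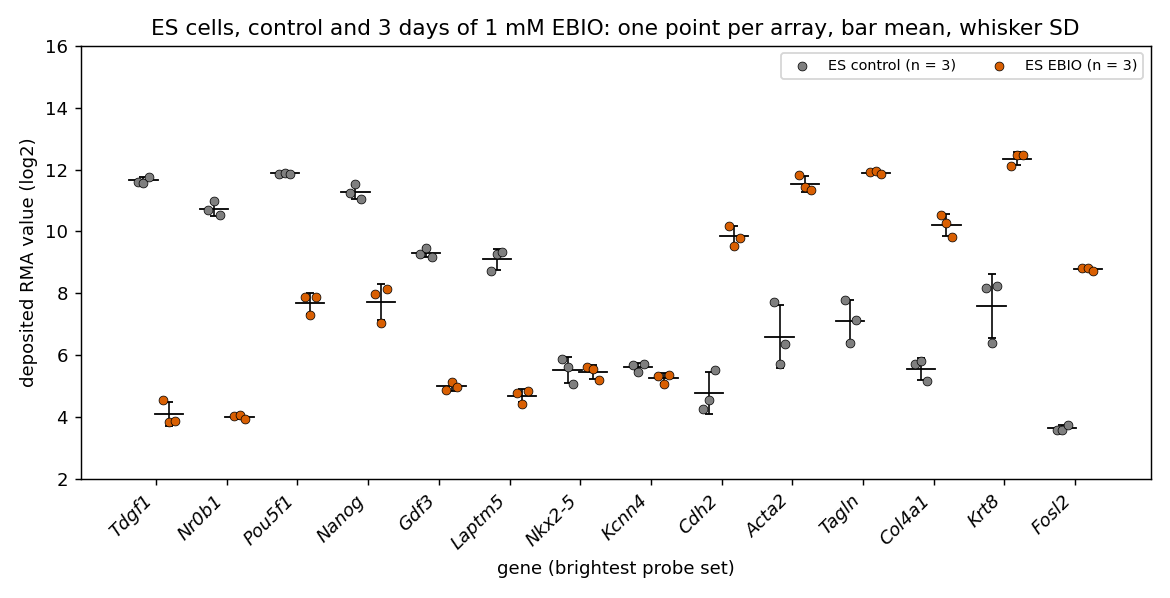
Deposited log2 value (vertical axis) of 14 genes (horizontal axis) on each ES array, with grey points for control (n = 3), orange points for EBIO (n = 3), bars for means and whiskers for SD. The EBIO arrays lie below the controls for Tdgf1, Nr0b1, Pou5f1 and Nanog and above them for Cdh2, Acta2, Tagln, Col4a1, Krt8 and Fosl2, while Nkx2-5 and Kcnn4 overlap or nearly touch and did not pass the test.

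Naive pluripotency genes fell: 16 of 18 tested members were lower and 1 was higher (17 called when adjusted over the list alone; median -3.27, camera adjusted p = 6.4e-11; adjusted p = 0.385 with an estimated correlation). The member that rose was Socs3 (1.17), a feedback inhibitor of cytokine signalling. Core pluripotency genes followed, with 13 of 16 lower and 1 higher (14 adjusted over the list alone; median -1.66, camera adjusted p = 1.9e-05; adjusted p = 0.385 with an estimated correlation). Nanog (-3.56) and Gdf3 (-4.31), a TGF-beta family ligand, fell, while Trim71 rose by 0.67. Of the 7 germ line genes tested 5 fell (5 adjusted over the list alone; camera adjusted p = 0.0023; adjusted p = 0.486 with an estimated correlation), among them Sycp3 and Mael (-2.61). Oxidative phosphorylation genes were lower in 12 of 22 and higher in 1 (14 adjusted over the list alone; median -0.36, camera adjusted p = 0.0067; adjusted p = 0.522 with an estimated correlation). Ndufv1 (-0.96) and Ndufb5 (-0.83) fell most there, and Cycs, the gene of cytochrome c, rose by 0.36 (adjusted p = 0.049).

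Extraembryonic endoderm genes rose in 8 of 11 and fell in 3 (11 adjusted over the list alone; median 1.31, camera adjusted p = 0.015; adjusted p = 0.385 with an estimated correlation). Its largest rises were of the basement membrane collagens Col4a2 (4.82) and Col4a1 (4.64), which many other cells make too, whereas Amn (-0.86) and Rhox5 (-0.78) fell. Without the filter on dim probe sets this list's median was 0.22 and its camera adjusted p was 0.056. Smooth muscle genes rose in 5 of 9 and fell in 1 (7 adjusted over the list alone, median 1.42). Camera's adjusted p for them was 0.017, and 0.486 with an estimated correlation. Acta2 and Tagln (4.80) led the rises, while Des, the desmin gene, fell by 0.65. With the mean of a gene's probe sets Des changed by -0.34 and was not called (adjusted p = 0.071, limma). Genes of cholesterol synthesis rose in 9 of 16, with no member called lower (9 adjusted over the list alone; median 0.66, camera adjusted p = 0.0023; adjusted p = 0.625 with an estimated correlation). Sc5d rose by 2.05 and Sqle, which encodes squalene epoxidase, by 1.79.

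The remaining lists did not pass camera in ES cells, although single members moved. Keratins of simple epithelia rose, Krt8 by 4.75 and Krt18 by 4.08, while the epithelial regulators Esrp1 (-2.55) and Grhl2 (-1.92) fell; the epithelial list had 4 higher and 4 lower of 11 (8 adjusted over the list alone). BMP targets had 6 higher and 2 lower of 10 (8 adjusted over the list alone): Id1 rose by 2.68 and Bambi by 2.43, while Smad6 (-1.06) and Bmp4 (-0.74) fell. Among ERK-responsive genes 7 of 18 rose and 6 fell (13 adjusted over the list alone), Phlda1 (4.03) and Egr1 (3.98) against Etv5 (-3.54) and Spry4 (-1.71). Glycolysis and hypoxia genes had 11 higher and 3 lower of 24 (19 adjusted over the list alone; camera adjusted p = 0.056), with P4ha1 at 2.62, the glucose transporter gene Slc2a1 at 2.12, Pdk1 at -1.99 and Aldoc at -1.42. Imprinted genes rose in 7 of 13 and fell in 2 (9 adjusted over the list alone), Igf2 by 3.11 and Peg10 by 2.73, against Phlda2 (-3.23) and Mest (-0.77).

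Endothelial genes had 6 lower and 1 higher of 14 (7 adjusted over the list alone; camera adjusted p = 0.052, and 0.047 with the replicate number as a block). Pecam1 (-2.92), which ES cells also express, and Tek (-1.24) fell, and Flt1, a VEGF receptor gene, rose from 5.08 to 6.28. Of the macrophage and leukocyte genes 3 of 6 fell (4 adjusted over the list alone), including Laptm5 (-4.42). Fibroblast and matrix genes had 3 higher and 1 lower of 9 (4 adjusted over the list alone), Vim (3.18) and Col5a1 (1.47) against Tgfbi (-1.44). Trophoblast genes had 5 higher and 1 lower of 11 (6 adjusted over the list alone), with Krt8 and Krt18 as the largest rises and Tfap2c (-2.03) as the fall. Formative and primed epiblast genes had 2 higher, Cdh2 and Pou3f1 (1.05), and 6 lower of 14 (8 adjusted over the list alone), with Dnmt3a at -1.89. Primitive streak and early mesoderm genes had 1 higher and 2 lower of 10 (3 adjusted over the list alone); Nodal (-3.12) and Fgf17 (-1.94) fell and Snai1 rose by 0.89.

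Cell cycle lists did not pass camera in ES cells. Mitosis genes fell in 7 of 19 (7 adjusted over the list alone), among them Nusap1 (-1.09), a spindle protein gene, and Cdc20 (-0.66). DNA replication genes had 3 higher and 7 lower of 17 (11 adjusted over the list alone), Pola1 (-1.68) and Mcm3 (-1.09) against Ccne2 (1.63) and Slbp (0.83). The p53 targets had 6 higher and 5 lower of 15 (12 adjusted over the list alone): Perp (1.87) and Sesn1 (1.07) rose, Gtse1 (-1.05) and Eda2r (-0.89) fell. Unfolded protein and stress response genes had 4 in each direction of 20 (8 adjusted over the list alone), from Cth (-4.47) and Herpud1 (-0.94) to Atf3 (1.57) and Hspa5 (1.05). NRF2 and xenobiotic genes had 2 higher and 6 lower of 12 (8 adjusted over the list alone), with Gsta4 at -2.48, Gstm1 at -1.88, Hmox1 at 0.95 and Srxn1 at 0.85. Wnt targets had 1 higher and 2 lower of 6 (3 adjusted over the list alone), Dkk1 (1.06) against Ccnd1 (-3.28) and Notum (-0.54). Neural genes had 5 higher and 2 lower of 17 (7 adjusted over the list alone): Nefl (1.48) and Ncam1 (1.44) rose, Stmn3 (-2.21) and Pax6 (-1.71) fell.

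No list of heart or channel genes passed camera in ES cells. The cardiac contractile list had 4 higher and 3 lower of 14 (7 adjusted over the list alone), with Tnnc1 at 1.35, Nppb at 1.16, Ttn at -1.30 and Myl7 at -0.47. Cardiac transcription factors had 1 higher of 7 (0 adjusted over the list alone in limma, 1 at an unadjusted p under 0.05). Pacemaker and conduction genes had 2 higher, Cacna1h (0.94) and Bves (0.54), and 1 lower, Tbx3 (-1.35), of 11 (3 adjusted over the list alone). With the mean of a gene's probe sets Bves changed by 0.23 and was not called (adjusted p = 0.078, limma). Skeletal muscle genes had 1 in each direction of 6 (2 adjusted over the list alone). Of the calcium-activated potassium channel genes 1 of 6 rose (1 adjusted over the list alone). Kcnn1 (-0.34, adjusted p = 0.16), Kcnn3 (-0.27, adjusted p = 0.29) and Kcnn4 (-0.36, adjusted p = 0.059) were not called; with the replicate number as a block Kcnn4 had an adjusted p of 0.021. Kcnn2, Myh6 and Shox2 were too dim to be tested, at means between 3.64 and 4.33. Definitive endoderm and hepatic genes (7 tested), erythroid genes (6) and cartilage genes (5) had no call in limma; at an unadjusted p under 0.05 the counts were 0, 0 and 1.

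In ES cells none of the 7 lists past camera held with an estimated correlation (3 at an unadjusted p under 0.05). That test had 4 residual degrees of freedom. Fry called all 7 in the same direction, but it called 23 of the 33 lists tested. For 4 lists not called by camera (neural, cardiac contractile, Wnt targets and epithelial) the median and mean differed in sign. The 3' minus 5' difference of Actb probe sets, a measure of RNA integrity, was 0.42 ± 0.09 in controls and 0.14 ± 0.06 with EBIO (SD, n = 3 each), while that of Gapdh was -0.01 and 0.02. The passage-27 control array correlated least with its replicates (0.982 and 0.987); without both passage-27 arrays 2802 genes rose and 2563 fell.

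The next comparison, the one closest to the series' title, asked what 10 days of EBIO did to differentiating cells. Of the cardiac contractile genes 26 of 29 rose; 18 of 20 fibroblast genes and all tested macrophage (14), endothelial (14), epithelial (12) and endoderm and liver genes (12) fell. Camera called these lists at its preset correlation, and none with an estimated correlation (adjusted p = 0.245 to 0.321). Nppa, the gene of atrial natriuretic peptide, rose by 7.06 ± 0.08 (SE), to 13.07 ± 0.06 (SD, n = 2 each, adjusted p = 1.5e-06, limma), 134-fold. Lum, which encodes the matrix proteoglycan lumican, fell from 12.05 ± 0.19 to 3.76 ± 0.17 (n = 2 each), at least 314-fold. C1qb, a complement gene of macrophages, fell from 12.04 ± 0.26 to 4.09 ± 0.12 (n = 2 each), at least 247-fold; both genes ended at the dim end of the arrays.

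Of 12338 genes tested in differentiated cells, 4111 rose and 4023 fell. Large changes were mostly falls: 1533 genes fell and 778 rose by at least 2-fold, and 154 fell and 16 rose by at least 16-fold. After Nppa the largest rises were those of Ttn (5.10), the gene of titin, Myl1 (4.74), Cyp1a1 (4.72), a xenobiotic-metabolising cytochrome, the calcium release channel gene Ryr2 (4.62) and Sphkap (4.54). After Lum the largest falls were those of Lyz1 (-8.26), C1qb (-7.95), Saa3 (-7.95), Ifitm3 (-7.69) and Col1a2 (-7.61). Lum, Lyz1, C1qb and Ifitm3 ended under the array medians of 5.59 and 5.61 and Saa3 near them (5.37). These falls are therefore lower bounds and their order is not resolved. Cyp1a1 began at 4.24, under the control array medians of 5.66 and 5.68, so its rise is a lower bound too and its rank is not resolved. Standard errors of the named genes' changes ran from 0.07 to 0.30. Fitted together with the ES arrays, 2577 genes rose, and a filter at the 75th percentile left 2529 falls.

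**Figure D2:**
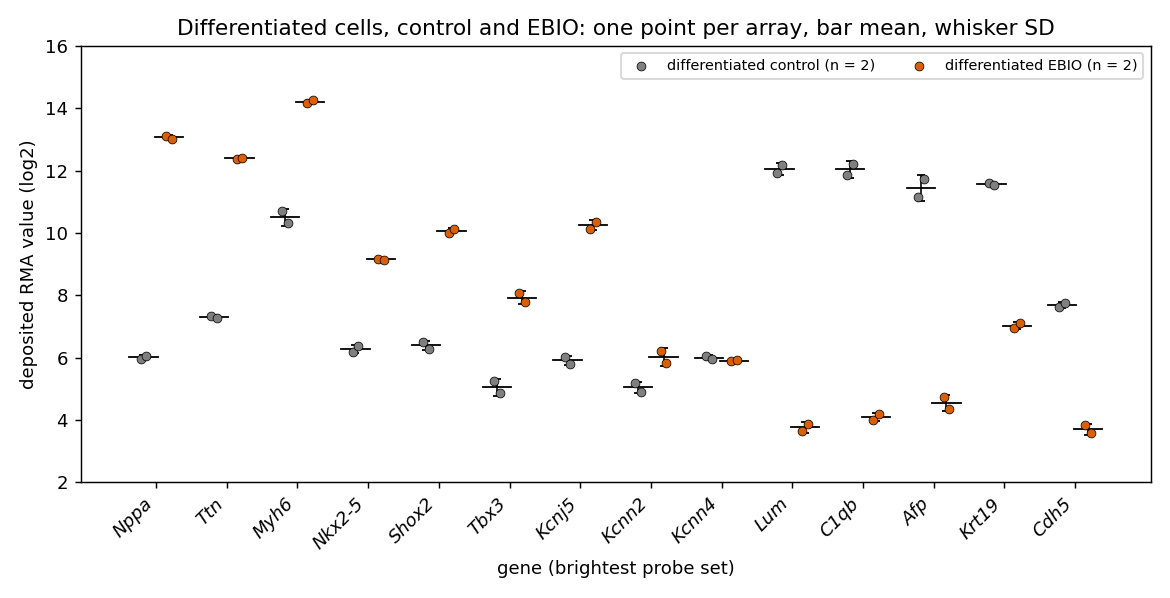
Deposited log2 value (vertical axis) of 14 genes (horizontal axis) on each differentiated array, with grey points for control (n = 2), orange points for EBIO (n = 2), bars for means and whiskers for SD. Nppa, Ttn, Myh6, Nkx2-5, Shox2, Tbx3, Kcnj5 and Kcnn2 lie higher with EBIO, Lum, C1qb, Afp, Krt19 and Cdh5 lie lower, and Kcnn4 differed by -0.10 and was not called.

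Cardiac contractile and calcium handling genes rose in 26 of 29 and fell in 1 (27 adjusted over the list alone; median 3.13, camera adjusted p = 5.1e-11; adjusted p = 0.245 with an estimated correlation). Nppa and Ttn led them, and Myoz2 fell by 0.89. Myh6, a myosin heavy chain gene of the heart, rose from 10.50 ± 0.27 to 14.21 ± 0.06 (n = 2 each, 13.1-fold). It ended close to the array maximum of 14.59, so its rise is understated if the probe set was saturated. Cardiac transcription factors rose in 9 of 12 (9 adjusted over the list alone; median 1.47, camera adjusted p = 0.00025; adjusted p = 0.245 with an estimated correlation). Myocd, a coactivator of muscle genes, rose by 3.95, Isl1, a factor of second heart field and sinus node cells, by 3.43, and Nkx2-5 by 2.87. Pacemaker and conduction genes rose in 11 of 14 and fell in 1 (13 adjusted over the list alone; median 1.71, camera adjusted p = 0.00013; adjusted p = 0.245 with an estimated correlation). Kcnj5, a subunit of the acetylcholine-gated potassium channel, rose by 4.34 and Popdc2 by 3.90. Shox2, a sinus node transcription factor, rose from 6.39 ± 0.16 to 10.07 ± 0.09 and Tbx3, which represses working myocardial genes in the conduction system, from 5.04 ± 0.27 to 7.92 ± 0.21 (n = 2 each). Tbx3 began under the control array medians of 5.66 and 5.68, so its rise is a lower bound. The member that fell was Cacna1g (-1.29), a T-type calcium channel gene.

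Oxidative phosphorylation genes rose in 21 of 22 (22 adjusted over the list alone; median 0.51, camera adjusted p = 1.8e-05; adjusted p = 0.394 with an estimated correlation), Cycs by 0.98 and Ndufs4 by 0.83. Among calcium-activated potassium channel genes 2 of 5 rose and 1 fell (3 adjusted over the list alone). Kcnn2, a small-conductance channel gene, rose from 5.04 ± 0.19 to 6.01 ± 0.28 (n = 2 each), Kcnmb4 rose by 0.69, and Kcnn1 fell by 0.68. Kcnn2 began under the control array medians of 5.66 and 5.68 and ended little above the EBIO array medians of 5.61 and 5.59. It was thus dim in both groups, and its rise is a lower bound. Kcnn4 changed by -0.10 (adjusted p = 0.28, not called). Kcnn3, Pou5f1 and Nanog were too dim to be tested.

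Genes of connective tissue fell: 18 of 20 fibroblast and matrix genes were lower and 1, Fn1 (0.29), was higher (19 adjusted over the list alone; median -4.46, camera adjusted p = 6.2e-09; adjusted p = 0.245 with an estimated correlation). All 14 macrophage and leukocyte genes fell (14 adjusted over the list alone; median -5.91, camera adjusted p = 9.8e-09; adjusted p = 0.321 with an estimated correlation), including C1qb and Laptm5 (-6.81). All 14 endothelial genes tested fell (14 adjusted over the list alone; median -2.06, camera adjusted p = 2.2e-06; adjusted p = 0.245 with an estimated correlation), including Cdh5 (-3.99), the gene of VE-cadherin, and Tek (-3.99). All 12 epithelial genes fell (12 adjusted over the list alone; median -2.07, camera adjusted p = 1.8e-05; adjusted p = 0.321 with an estimated correlation), with Krt19 at -4.55 and Cdh1 at -3.46. The 12 tested genes of definitive endoderm and liver fell too (12 adjusted over the list alone; median -2.19, camera adjusted p = 1.8e-05; adjusted p = 0.245 with an estimated correlation), including Afp (-6.89), the fetal liver gene of alpha-fetoprotein, and Apoa1 (-4.08).

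Cell cycle genes were lower. Mitosis genes fell in 18 of 19 (18 adjusted over the list alone; median -0.67, camera adjusted p = 1.8e-05; adjusted p = 0.575 with an estimated correlation), Nusap1 (-1.15) and the cyclin gene Ccnb2 (-1.07) among them. DNA replication genes fell in 12 of 17 and rose in 1 (13 adjusted over the list alone; median -0.63, camera adjusted p = 0.0097; adjusted p = 0.575 with an estimated correlation), with Mcm3 at -0.98, Mcm4 at -0.97 and Rrm2 at 0.38. Cholesterol synthesis genes fell in 14 of 16 (14 adjusted over the list alone; median -0.81, camera adjusted p = 0.00014; adjusted p = 0.245 with an estimated correlation), Stard4 (-1.77) and Insig1 (-1.16) among them. The p53 targets fell in 11 of 16 and rose in 1 (12 adjusted over the list alone; median -0.45, camera adjusted p = 0.011; adjusted p = 0.321 with an estimated correlation), with Pmaip1 at -1.93, Fas at -1.82 and Bbc3 at 0.29. Glycolysis and hypoxia genes fell in 15 of 24 and rose in 5 (20 adjusted over the list alone; median -0.75, camera adjusted p = 0.014; adjusted p = 0.606 with an estimated correlation), Aldoc (-3.65) and Egln3 (-3.30) against Hk1 (1.68) and Slc2a1 (0.84). Wnt targets fell in 7 of 9 and rose in 1 (8 adjusted over the list alone; median -0.76, camera adjusted p = 0.032; adjusted p = 0.370 with an estimated correlation), Ccnd1 (-3.51), the gene of cyclin D1, and Dkk1 (-1.86) against Znrf3 (0.74). With the mean of a gene's probe sets the Wnt list had a camera adjusted p of 0.13.

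Other lists moved in both directions and did not pass camera in differentiated cells. Smooth muscle genes had 6 higher and 4 lower of 11 (10 adjusted over the list alone), Synpo2 (3.01) and Myl9 (2.44) against Mylk (-3.12) and Pdgfrb (-1.71). Neural genes had 9 higher and 4 lower of 16 (13 adjusted over the list alone), Pax6 (1.68) and Map2 (1.53) against Gap43 (-2.41) and Zic1 (-1.71). Extraembryonic endoderm genes had 4 higher and 7 lower of 15 (12 adjusted over the list alone), with Cited1 at 4.10, Col4a2 at 1.00, Pdgfra at -4.29 and Srgn at -3.76. NRF2 and xenobiotic genes split evenly, 7 higher and 7 lower of 14 (14 adjusted over the list alone): Cyp1a1 and Cyp1b1 (1.47) rose, Gsta3 (-4.04) and Ephx1 (-3.99) fell. ERK-responsive genes had 4 higher and 9 lower of 19 (14 adjusted over the list alone), with Egr2 (1.21) and Egr1 (1.16) among the rises and Etv5 (-1.56) and Spred2 (-0.95) among the falls. Unfolded protein and stress response genes had 3 higher and 8 lower of 19 (11 adjusted over the list alone), Asns (0.99) and Herpud1 (0.37) against Trib3 (-1.51) and Chac1 (-1.36). BMP targets had 4 higher and 5 lower of 10 (9 adjusted over the list alone): Msx2 (1.70) and Smad6 (0.60) rose, Id3 (-0.77) and Bmp4 (-0.73) fell.

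Trophoblast genes had 2 higher and 5 lower of 10 (7 adjusted over the list alone), from Krt7 (-6.34) and Plac1 (-2.68) to Peg10 (2.64) and Gata3 (0.31). Imprinted genes had 2 higher, Peg10 and Igf2r (1.39), and 6 lower of 15 (8 adjusted over the list alone), among them Sgce (-1.18) and Zim1 (-0.61). Primitive streak and early mesoderm genes fell in 4 of 10 (4 adjusted over the list alone), including Pdgfra and Fgf8 (-2.74). Naive pluripotency genes had 2 higher, Tbx3 and Klf5 (0.70), and 5 lower of 10 (7 adjusted over the list alone), with Pecam1 at -2.90 and Socs3 at -2.87. Core pluripotency genes had 2 higher and 2 lower of 7 (4 adjusted over the list alone), Trim71 (0.42) and Utf1 (0.30) against Sox2 (-2.30) and Mycn (-1.23). Formative and primed epiblast genes had 2 higher and 4 lower of 9 (6 adjusted over the list alone), Cdh2 (1.48) and Pim2 (1.38) against Lef1 (-1.64) and Grhl2 (-1.50). Cartilage genes fell in 4 of 5 (4 adjusted over the list alone), including Col9a2 (-2.41) and Col11a1 (-2.09). Skeletal muscle genes had 3 higher and 2 lower of 7 (5 adjusted over the list alone): Acta1 (1.26) and Myh8 (1.17) rose, Tnni2 (-0.86) and Casq1 (-0.36) fell. Erythroid and haematopoietic genes had 1 higher, Itga2b (0.25), and 2 lower, Cd34 (-4.19) and Tal1 (-1.99), of 5 (3 adjusted over the list alone). The call of Itga2b was lost with the replicate block (adjusted p = 0.053, limma) and when any 1 array was left out. Of 2 germ line genes 1 fell (1 adjusted over the list alone).

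None of the 15 lists past camera in differentiated cells held with an estimated correlation (6 at an unadjusted p under 0.05). That test had 2 residual degrees of freedom, so the loss need not come from correlation. The fibroblast list's estimate was -0.003, under the preset 0.01, yet camera's unadjusted p went from 3.9e-10 to 0.021. Fry called all 15 in the same direction, but it called 29 of the 32 lists tested, so this adds little. For BMP targets, imprinted genes, core pluripotency and early mesoderm genes, none called by camera, the median and mean differed in sign. The Actb 3' minus 5' difference was 0.43 ± 0.04 in controls and 0.46 ± 0.02 with EBIO (SD, n = 2 each). In simulated data of this design, with 200 genes changed, unchanged genes made up 8.52% of calls against a nominal 5%. Their share among the real calls, which covered 65.9% of genes, was not measured.

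**Figure D3:**
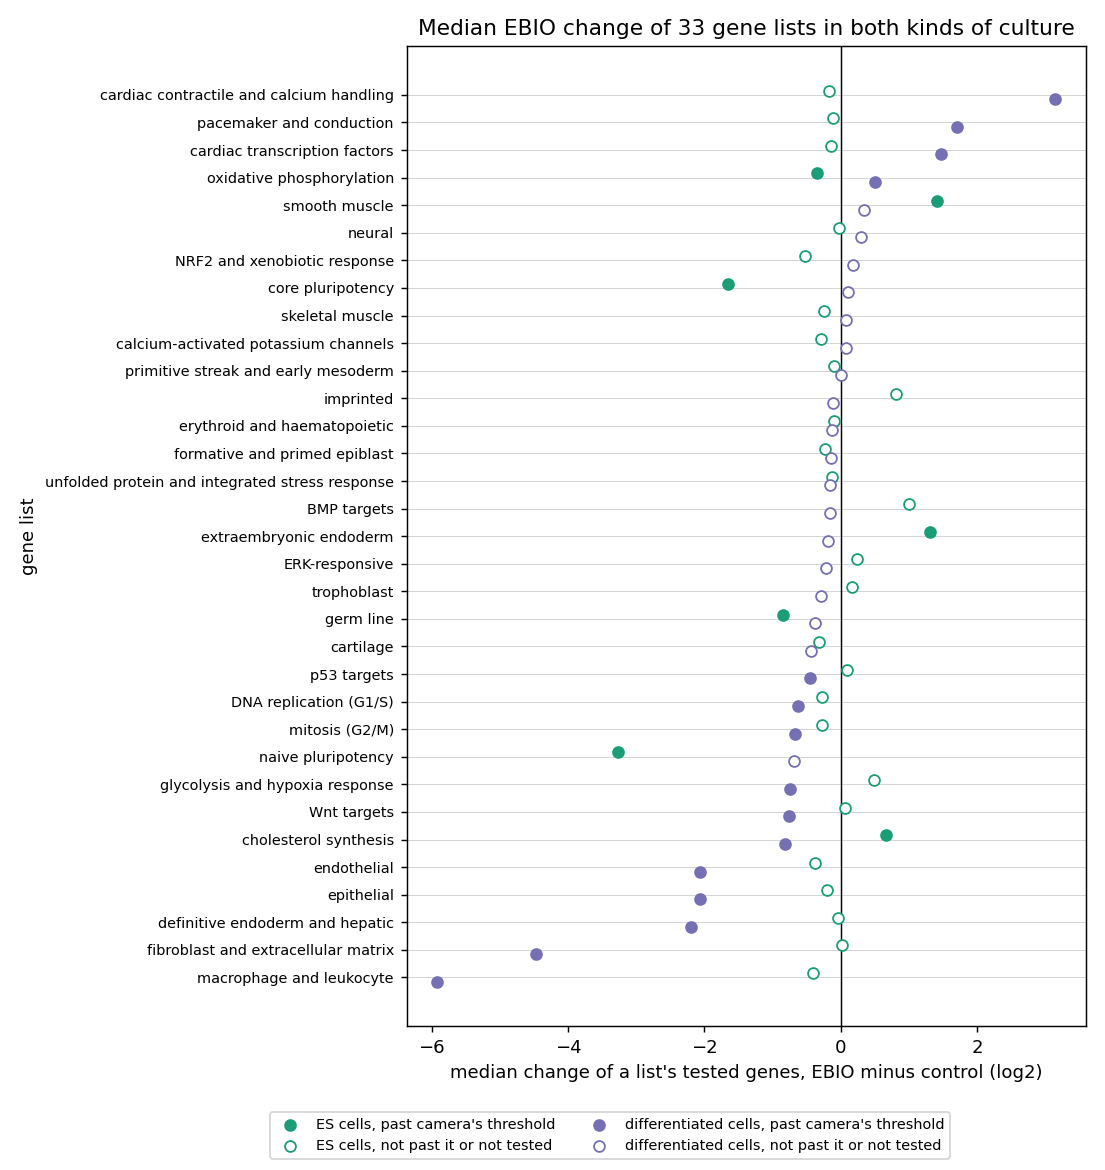
Median log2 change with EBIO (horizontal axis) of the tested members of each of 33 gene lists (vertical axis), green for ES cells and violet for differentiated cells; filled points passed camera's threshold. Cardiac contractile genes (3.13) and macrophage genes (-5.91) mark the ends for differentiated cells, and naive pluripotency genes (-3.27) and smooth muscle genes (1.42) for ES cells.

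The responses to EBIO differed between the culture stages, by a test of the difference itself. Of 22 oxidative phosphorylation genes 12 fell in ES cells and 21 rose in differentiated cells (median difference 0.81, camera adjusted p = 1.8e-07; adjusted p = 0.119 with an estimated correlation). Of 16 cholesterol synthesis genes 9 rose in ES cells and 14 fell in differentiated cells (median difference -1.59, camera adjusted p = 2.9e-05; adjusted p = 0.329 with an estimated correlation). Tbx3 fell by 1.35 in ES cells and rose by 2.88 in differentiated cells, a difference of 4.23 ± 0.26 (SE; adjusted p = 2.9e-07, limma). Krt19 rose by 3.78 in ES cells and fell by 4.55 in differentiated cells, a difference of -8.33 ± 0.30 (SE; adjusted p = 9.5e-09).

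Of 13712 genes tested for the difference, the EBIO effect was higher in differentiated than in ES cells for 2809 and lower for 3428. Across the 10925 genes tested in both, the effects correlated at r = 0.204 (Spearman 0.216); genes are not independent replicates and no p is given. Both effects were called higher for 1300 genes and lower for 1024, where independent calls would give 964 and 684. Opposite calls numbered 721 (higher in ES cells, lower in differentiated cells) and 518 (the reverse), against 840 and 784 for independent calls. The duration of EBIO differed too (3 and 10 days), the dose is unstated for differentiated cells, and the arrays of the stages were normalized apart, with a wider spread of values in the differentiated set.

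The remaining comparison set untreated differentiated cells against untreated ES cells, the background to the EBIO effects. Connective tissue genes were far higher in differentiated cells and pluripotency genes far lower. Col3a1 measured 3.42 ± 0.11 in ES cells (SD, n = 3) and 14.01 ± 0.01 in differentiated cells (n = 2), and Nanog 11.27 ± 0.24 and 4.09 ± 0.01. Differences of the same order were seen for Plagl1 (10.42), Col1a1 (9.47), Cdh11 (9.46), Dcn (8.98) and Col1a2 (8.91), and for Dppa2 (-7.15), Eras (-7.12), Tdgf1 (-7.12), Zfp42 (-7.04), Nr0b1 (-6.84) and Pou5f1 (-6.68). Myh6 (6.35) and Shox2 (2.74) were higher and Tbx3 (-3.12) lower without any EBIO. After quantile normalization of all arrays together these differences kept their signs (Col3a1 10.22, Nanog -7.77, Myh6 5.33, Shox2 1.82, Tbx3 -4.22). The small differences did not all keep theirs: Nkx2-5 went from 0.76 to -0.75, Kcnn1 from 0.59 to -0.74, Kcnn2 from 0.72 to -0.10, Kcnn3 from 0.06 to -1.13 and Kcnn4 from 0.38 to -1.07.

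Because the stages were normalized apart, the count of calls here depends on the scaling. In the planned fit 10844 of 13712 genes were higher and 1103 lower in differentiated cells (90.8% higher), with a median difference of 1.30 over all genes tested; after a new quantile normalization 4946 were higher and 5626 lower (46.8% higher, median -0.11). Camera, which compares a list with all other genes, called 11 of 33 lists here, 6 of them with an estimated correlation, core pluripotency first (adjusted p = 0.00103 with it); fry, which follows the shift of all genes, called 7 of the 11 in the same direction. The EBIO effect in ES cells correlated with this stage difference at r = 0.605 across 12096 genes. Both comparisons use the same ES control arrays, which alone gave r = 0.447 in simulations of unchanged groups; the covariance was 0.810 against 0.0138 simulated. With the 3 control arrays divided so that each effect had controls of its own, r was 0.533 to 0.600 and the covariance 0.720 to 0.829 over the 6 divisions, which were added after seeing the data.

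**Figure D4:**
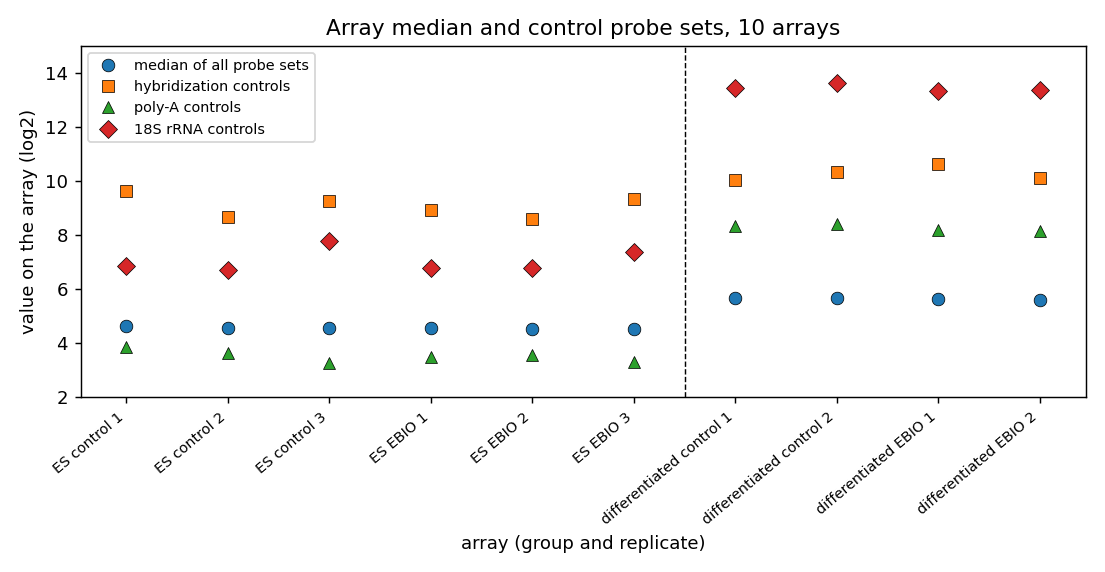
Log2 value (vertical axis) of the array median and the median of 3 classes of control probe sets on each of the 10 arrays (horizontal axis); the dashed line parts ES from differentiated arrays. The poly-A controls lie between 3.26 and 3.86 on the ES arrays and between 8.14 and 8.42 on the differentiated arrays, and the 18S controls between 6.71 and 7.77 and between 13.33 and 13.62.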

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

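The tests of explanations in this part (on added control transcripts, marker genes and fibroblast transcripts) were chosen after the results were seen. In ES cells EBIO called 5413 genes in limma. The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split alone (1 of 10) gave so many, and the highest of the others gave 0 (at most 532 at an unadjusted p under 0.05). The other splits mix treated and untreated arrays, so the EBIO effect widens their spread within groups. Few calls were bound to follow, and the contrast is no measure of calls without an effect.

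A test of the difference between the EBIO effects, differentiated minus ES, picked out the following results. The effect was higher in differentiated cells for 2809 genes and lower for 3428. Of the gene lists, 18 passed camera on this difference; each median difference is followed by the adjusted p with an estimated correlation. Above 0 were naive pluripotency (3.39; adjusted p = 0.0745), cardiac contractile (2.77; adjusted p = 0.0593), core pluripotency (1.71; adjusted p = 0.0695), pacemaker (1.24; adjusted p = 0.0593), germ line (1.08; adjusted p = 0.188), cardiac transcription factor (0.99; adjusted p = 0.0745) and oxidative phosphorylation (0.81; adjusted p = 0.119) genes. Below 0 were macrophage (-5.50; adjusted p = 0.0593), fibroblast (-4.09; adjusted p = 0.0279), definitive endoderm and hepatic (-2.41; adjusted p = 0.0695), epithelial (-2.26; adjusted p = 0.188), cholesterol synthesis (-1.59; adjusted p = 0.329), glycolysis and hypoxia (-1.21; adjusted p = 0.329), trophoblast (-1.11; adjusted p = 0.181), endothelial (-1.08; adjusted p = 0.119), p53 target (-0.91; adjusted p = 0.329), extraembryonic endoderm (-0.90; adjusted p = 0.0899) and mitosis (-0.51; adjusted p = 0.294) genes. With an estimated correlation the fibroblast list alone kept its call. The p53 list also lost its call with the replicate block (camera adjusted p = 0.052). A gene at the dim end in 1 stage cannot be seen to fall there, which leaves the fall in the other stage as the difference. Of 18 naive, 16 core and 7 germ line genes 10, 7 and 2 were bright enough to test in differentiated cells, and of 20 fibroblast and 14 macrophage genes 9 and 6 in ES cells, so these differences do not show opposite responses.

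Of 180 named genes 143 passed the threshold of the difference. Given here are the 34 of them that were called in opposite directions in the 2 stages. Genes that rose in ES cells and fell in differentiated cells, with the difference, were Krt19 (-8.33), Anxa2 (-5.57), Fosl2 (-5.53), Krt8 (-5.19), Krt18 (-4.83), Socs3 (-4.04), Gap43 (-3.82), Igf2 (-3.48), P4ha1 (-3.40), Id1 (-3.23), Id3 (-3.09), Stard4 (-2.98), Dkk1 (-2.91), Col5a1 (-2.89), Bambi (-2.80), Sc5d (-2.77), Ncam1 (-2.40), Sgce (-2.32), Sqle (-2.23), Sesn1 (-1.97), Flt1 (-1.94), Hmox1 (-1.69), Snai1 (-1.65) and Hspa5 (-1.31). Genes that fell in ES cells and rose in differentiated cells were Ttn (6.40), Tbx3 (4.23), Pax6 (3.39), Utf1 (2.89), Myl7 (2.57), Stmn3 (2.47), Smad6 (1.66), Ndufv1 (1.56), Ndufb5 (1.32) and Herpud1 (1.31). Of these, Utf1 lost its call in differentiated cells without control 1 or EBIO 1 (adjusted p = 0.115 each) and with the replicate block (adjusted p = 0.052), and Herpud1 its call in ES cells without ES control 2 (adjusted p = 0.066). Some of the 34 differences come mostly from ES cells. In differentiated cells Anxa2 changed by -0.52, Fosl2 by -0.40, Krt8 by -0.43, Stmn3 by 0.26 and Utf1 by 0.30. Others do not, such as Krt19 (-4.55) and Ttn (5.10) in differentiated cells. Over all genes 1239 were called in opposite directions and passed the difference. Opposite calls (721 and 518 by direction) were fewer than independent calls would give (840 and 784).

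In probe sets outside the comparisons, the poly-A control transcripts lay 4.78 higher on the untreated differentiated than on the untreated ES arrays, and the 18S rRNA controls 6.54 higher. Most genes were also higher there, by a median of 1.30. Separate processing and normalization of the array sets could account for that shift: the hybridization controls, added in fixed amounts, were 1.01 higher as well, and this test could have come out near 0. The poly-A controls, meant to be added before labelling, were at the dim end on all 6 ES arrays. A shift common to the set does not account for the largest differences, such as Nanog (-7.77), Pou5f1 (-7.62) and Col3a1 (10.22) after quantile normalization of all arrays together. For differences near the size of the shift, stage and array set cannot be told apart, since each stage lies in a set of its own.

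Marker genes of macrophages, fibroblasts, epithelium and endothelium fell together in EBIO-treated differentiated cells; dilution of all other cells alike by more cardiomyocytes would lower them by the same amount, as far as the dim end of the arrays lets a fall be seen. Neural genes were picked with their values already seen, after 2 earlier tests on other genes had decided nothing. Of these, 7 had controls at least 1 log2 unit over the median of the EBIO arrays. The macrophage fall (-5.91, or down to that median) would leave a level that 6 of them lay above, by a median of 2.58 over the 7. Their own median change was -0.77. For these 7 genes this goes against dilution by the macrophage amount only. The macrophage list fell most of all lists, so others were likely to lie above that level. Dilution of all other cells alike by a smaller amount is not decided by this comparison. Smooth muscle (9 genes, 3.36), extraembryonic endoderm (13 genes, 3.42) and trophoblast genes (6 genes, 2.49) also lay above that level. The last 2 lists share genes (Gata4, Gata6 and Hand1) with the cardiac transcription factors. Epithelial (11 genes, 0.91) and fibroblast genes (20 genes, 0.83) lay less far above it, and endothelial (13 genes, -0.20) and endoderm and liver genes (10 genes, -0.09) near it. A common loss of part of the cell types therefore stays open. Expression of the neural, smooth muscle, extraembryonic endoderm and trophoblast genes in cardiomyocytes was not tested. A difference in labelling or hybridization is argued against by the added controls, which differed by at most 0.318 between the groups. Fewer cells of these kinds, or less RNA of these genes per cell, may each underlie the falls and remain open, as bulk RNA counts no cells; an effect of EBIO on either was not tested.

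Of 9 smooth muscle genes 5 rose and 1 fell in EBIO-treated ES cells (camera's call was lost with an estimated correlation, adjusted p = 0.486). Fibroblasts mixed into the treated cultures would bring their abundant transcripts, but of Col1a1, Col1a2, Col3a1, Lum, Dcn and Postn none rose by more than 0.031 and all stayed at means of 4.68 or lower, against 11.81 or higher in untreated differentiated cells. The hybridization controls differed by a median of 0.164 in size between the ES groups, which argues against a hybridization difference left after normalization. The poly-A controls (difference 0.116) lay at the dim end and say nothing on labelling. The Actb 3' minus 5' difference went from 0.42 to 0.14 and that of Gapdh from -0.01 to 0.02. A response of the ES cells themselves to EBIO is a candidate explanation, found and examined on the same data.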

How the results depend on the processing

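All alternatives here were planned except the crossed pairing, the ES comparison without both passage-27 arrays, the division of the ES controls and the list tests after a new quantile normalization, which were chosen after seeing the data. No EBIO result past its threshold changed direction under an alternative run for it. In the stage difference Nkx2-5 and Kcnn1 to Kcnn4 changed sign after quantile normalization, with the values given beside them. In differentiated cells 2577 genes rose in a fit of all 4 groups and 2529 fell with a filter at the 75th percentile, which tests fewer genes. For differentiated against ES controls the higher calls went to 7138 (75th percentile filter), 6217 (median centring) and 4946 (new quantile normalization), and the lower calls to 2288 (no filter), 731 (75th percentile filter), 4398 (median centring) and 5626 (quantile normalization). The correlation of the EBIO effects was 0.150 without the filter and 0.189 after quantile normalization; that of the ES effect with the stage difference was 0.494 without the filter, 0.703 at the 75th percentile and 0.575 on average with ES controls of its own for each effect, which leaves fewer arrays to each. The cause of these shifts in correlation was not tested. Leaving out each array in turn gave 2393 to 2982 rises and 1997 to 2834 falls in ES cells, 3380 to 3540 and 3539 to 3575 in differentiated cells, 10347 to 10845 and 929 to 1236 for the stage difference, and 2088 to 3313 and 2855 to 3714 for the difference of EBIO effects; the correlations ran from 0.197 to 0.207 and from 0.595 to 0.627. In differentiated cells this leaves a lone array in 1 group, assumed to vary like the other group. With the replicate block 3333 genes rose and 3141 fell in ES cells, where the numbers pair the samples; among ES results it changed the call of Kcnn4 and the endothelial list, as given beside them, and no other, and it ended the call of the p53 list in the difference of EBIO effects (adjusted p = 0.052). In differentiated cells, where a pairing by number could not be shown, the block gave 3731 and 3761 and the crossed pairing 4076 and 4041. For the stage difference the block gave 10931 and 1287, and for the difference of effects 3334 and 3820. Calls of named genes near the threshold depend on single arrays: in ES cells Cycs lost its call without any array but ES control 3, and Srxn1 without any but EBIO 1. Bmp4, Ccne2, Coro1a, Des and Herpud1 lost theirs without ES control 2, Ccne2 also without EBIO 1, Coro1a without EBIO 3, and Des without ES control 1 or EBIO 3; with the mean of a gene's probe sets Bves, Cycs and Des lost theirs, and without both passage-27 arrays Kcnn1 gained a call (adjusted p = 0.034) while Coro1a (adjusted p = 0.069) and Srxn1 (adjusted p = 0.15) lost theirs. In differentiated cells Itga2b lost its call without any single array, Bbc3 without any but control 2, Utf1 and Gata3 without control 1 or EBIO 1, Casq1 without control 1 or EBIO 2, Rrm2 without control 2 or EBIO 1, Fn1 without EBIO 2 and Zim1 without control 2; the block ended the calls of Itga2b (adjusted p = 0.053) and Utf1 (adjusted p = 0.052). Of lists near the threshold in ES cells, the endothelial one gained a call without ES control 3, EBIO 1 or EBIO 2, without the filter, with the mean of probe sets and without both passage-27 arrays, and the glycolysis and hypoxia one without EBIO 2 or EBIO 3, without the filter and after quantile normalization; in differentiated cells the cartilage one gained a call without EBIO 2 and without the filter, and for the difference of effects the Wnt one did without the filter. The p53 list lost its call in the difference of effects without ES EBIO 1 or differentiated control 1. Dim probe sets limit what can be seen: Kcnn2, Myh6 and Shox2 in ES cells and Kcnn3, Pou5f1 and Nanog in differentiated cells could not be tested.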

Other observations

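The tests in this part were all chosen after the results were seen, and its gene families, 24 with enough members in each comparison, were picked by symbol after seeing the data. In EBIO-treated ES cells the tropomyosin, actin and myosin light chain genes rose in 11 of 14 and fell in 1 (camera adjusted p = 0.00052; adjusted p = 0.448 with an estimated correlation), Tpm1 by 3.13, Tpm2 by 3.02 and Acta1 by 4.12. Annexins, calcium-dependent membrane-binding proteins, rose in 6 of 8 and fell in 1 (camera adjusted p = 0.0071; adjusted p = 0.567 with an estimated correlation), Anxa3 by 4.17. Mitochondrial ribosomal protein genes fell in 38 of 73 and rose in 5 (median -0.42, camera adjusted p = 0.0002; adjusted p = 0.946 with an estimated correlation). Cytosolic ribosomal protein genes fell in 10 of 44 (camera adjusted p = 0.0071; adjusted p = 0.914 with an estimated correlation), and interferon-induced Ifi genes in 5 of 10 (camera adjusted p = 0.016; adjusted p = 0.448 with an estimated correlation), with Ifitm3 at -5.66 and Ifitm2 at -2.07.

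In EBIO-treated differentiated cells the lysosomal cathepsin genes fell in 12 of 12 (camera adjusted p = 5.4e-05; adjusted p = 0.395 with an estimated correlation), from Ctss (-5.69) to Ctsl (-0.63). Serpins fell in 13 of 15, Serping1 by 6.15, and Serpini1 rose by 1.87 (camera adjusted p = 0.00015; adjusted p = 0.395 with an estimated correlation). Ifi genes fell in 12 of 17 and rose in 1, claudins, tight junction proteins, fell in 10 of 12, and S100 genes fell in 7 of 7, with S100a4 at -4.10 (each adjusted p = 0.395 with an estimated correlation). Collagens went both ways, 19 of 31 lower and 8 higher: Col6a1 fell by 5.54, while the basement membrane genes Col4a1 and Col4a2 rose by 0.76 and 1.00 (camera adjusted p = 0.002; adjusted p = 0.395 with an estimated correlation). Voltage-gated calcium channel genes rose in 6 of 12, Cacna2d2 by 4.02, Cacnb2 by 2.76 and Cacna1c by 1.71, and 1 fell (camera adjusted p = 0.035; adjusted p = 0.395 with an estimated correlation). Mitochondrial ribosomal protein genes rose in 35 of 73 and fell in 7 (camera adjusted p = 0.012; adjusted p = 0.583 with an estimated correlation). Annexins fell in 7 of 8 and rose in 1, Anxa6 (camera adjusted p = 0.0072, and 0.429 with an estimated correlation). Tropomyosin, actin and myosin light chain genes rose in 11 of 17 and fell in 3 (camera adjusted p = 0.0095, and 0.395 with an estimated correlation). Keratins fell in 11 of 20 and rose in 2 (camera adjusted p = 0.025, and 0.395 with an estimated correlation). Histone genes rose in 6 of 9 (camera adjusted p = 0.032, and 0.429 with an estimated correlation).

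Cyp1a1 was among the largest rises in EBIO-treated differentiated cells, from 4.24 to 8.95. One hypothesis is that EBIO, or a product of it, activates the aryl hydrocarbon receptor, of which Cyp1a1 is a target, in both kinds of culture. Of 9 target genes listed for this, the 4 tested in differentiated cells rose: Cyp1a1 (4.72), Cyp1b1 (1.47), Tiparp (1.03) and Nqo1 (0.76). Cyp1a1 prompted the hypothesis, so its own rise is no test of it. Targets too dim to test there changed less: Ahrr by 0.42, Cyp1a2 by 0.25 and Aldh3a1 by 0.12. Of all 12338 genes tested in differentiated cells 4111 rose, so a few rises among targets carry little weight. In ES cells 0 of the 2 targets tested rose in limma, at an unadjusted p too, and both fell, Tiparp by 0.79 and Nqo1 by 1.67, while Cyp1a1 stayed at 3.58 and 3.62 on the dim end. Other measured targets, too dim to test in ES cells, changed little: Cyp1b1 by 0.25, Cyp1a2 by -0.10, Ahrr by -0.14 and Aldh3a1 by -0.30. No measured target thus rose clearly there. With 2 tested targets and the rest at the dim end, the ES data may still not decide the hypothesis. A rise within the differentiated cells alone, or a change in the cells present, remains open.

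The EBIO effect in ES cells ran in the direction of the stage difference. If the shared ES control arrays were the source, the covariance across genes would fall toward 0 once each effect had control arrays of its own; it was 0.810 with all controls shared and 0.720 at the lowest of the 6 divisions. Sharing the controls is thus argued against as the whole source. A change in the direction of differentiation is a candidate explanation, and a role of the separate array sets stays open.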
